A study of Rattus norvegicus with 28 samples.

How the data were processed

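Total RNA from rat superior olivary complex (SOC) and from whole brain was hybridised to Agilent 2-colour whole-genome oligonucleotide arrays. The data comprised 28 samples, of which 27 fell into 4 groups: SOC at postnatal day 4 (P4, n = 6) and day 25 (P25, n = 9), and whole brain at P4 (n = 6) and P25 (n = 6). A single SOC sample from P0 entered no comparison. Per the labels' protocols, SOC tissue was taken from vibratome slices in cold buffer and extracted with a lipid tissue kit, while each brain RNA came from 1 entire brain and another kit of the same maker. RNA of 1 SOC sample came from 1 animal at P25, 2 pooled animals at P4 and 4 at P0. Tissue and handling therefore cannot be told apart in any comparison of SOC with brain, and pooled RNA evens out differences between animals in SOC at P4. The labels number the samples as replicates without stating that no animal gave more than 1 sample, so p-values measure the spread between these samples.

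The scanner files held 39 records of 29 different arrays on 11 slides, since 10 arrays were deposited under both of the samples they carried. The slides were scanned on 8 days, and each slide was scanned on 1 day only. Per the file headers, each value is the mean intensity of a spot and the median intensity of its local background in the Cy3 or Cy5 channel, read by Agilent Feature Extraction version 9.5.1.1 (version 8.1 per the submitters' processing notes). The headers also record that background subtraction was off, and the background used by that software was 0 for every spot. The authors deposited in addition processed values of linear intensity, in a table that holds 1 column per sample. Each of its 28 columns correlated at 0.993 or more (log2 scale, across probes) with the processed signal of the labelled channel, and the column medians lay between 92.5 and 146. Its scale is thus linear and it has no direction, but any step after Feature Extraction is not given in the sources used here, and it served as an alternative only. The dye of each sample came from the labels. SOC P25 replicate 4 was a technical dye swap labelled with 1 dye, and the channel on each of its 2 arrays was settled by that sample's own deposited column. On these arrays 19 channels held RNA that belongs to no sample of the series used here. They took part in normalization alone and in no value or test.

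Intensities were corrected with normexp (offset 50), normalized by loess within arrays with control spots at weight 0, and by quantiles of the average intensity between arrays (limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table). Single-channel log2 intensities were then taken. Control spots and spots marked as outliers by the scanner software (median 93, at most 213 per channel) were left out, and saturated spots were kept. The 10 spots of each of 263 repeated probes were averaged, as were the hybridisations of a sample (1 to 3). The above-background mark of Feature Extraction was set for 100% of spots and so could not serve as the planned filter. A probe was instead called above background where its mean signal exceeded the mean of the 153 negative-control spots by 2.6 SDs, a rule chosen after the files were seen. By that rule 52.4% to 91.6% of the 41012 probes were above background per sample. A sample with several hybridisations passed for a probe where at least 50% of them did. As a check on the rule, 8.61% of Cy3 and 20.6% of Cy5 values of 1111 olfactory receptor probes passed it, against 62.7% and 75.2% of all probes. A probe was tested where it passed in at least 50% of the samples of at least 1 group, which left 33081 probes, 156 of which were dropped for a missing value. The number of arrays limits the precision of every value.

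Probes were named through current RefSeq gene records by the accession in the systematic name (10768 probes) or in the accession column (276), by current symbol (4994) or by a unique synonym (931). The other 24043 kept the name in the file. For each gene the probe with the highest mean over the 4 groups was tested, giving 28279 genes, 11040 of them with an official symbol. Among 3824 genes with several tested probes, probes called at least 2-fold in opposite directions occurred for 0 genes in 4 of the comparisons and for 1 gene in SOC against brain at P25. Coordinates are those of the probes on the rat build rn4, as the files give them. Their position in exons or untranslated regions was not analysed here.

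Comparisons were fitted in 1 limma model over the 27 samples, with group means, the share of a sample's hybridisations in Cy5 as a covariate, and samples linked by a shared array as a random block (7 blocks of more than 1 sample, consensus correlation 0.355). The fit had 22 residual and 3.68 prior degrees of freedom, and the Cy5 term was called for 440 genes. Because of that term a fitted change can differ slightly from the difference of the group means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and counted where it also changed at least 2-fold. Log2 changes are given ± standard error, and group means of log2 intensity ± SD.

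Altogether 32 gene lists with 701 memberships were set down before the data were examined, as were the comparisons, the model, the rule for the genes named and all alternatives but 3. They covered cell types (mature oligodendrocyte and myelin, oligodendrocyte precursor, astrocyte, microglia, endothelial cell and pericyte, meninges and fibroblast, choroid plexus, red blood cell), states (cell division, immature neuron, immediate early and heat shock), regions (forebrain, cerebellum, brainstem transcription factors, Hox, monoamine and motor neuron) and functions (ion channels in 3 lists, receptors and transporters of glutamate, GABA and glycine, synaptic vesicle release, chloride and bicarbonate transport, calcium-binding proteins, ion pumps and energy supply, neurofilaments, neuropeptides, axon guidance, perineuronal net matrix, cholesterol synthesis and hereditary deafness). A gene can be on several lists, and 616 memberships were tested. Counts of members that rose or fell use the adjusted p without a minimum fold. By that threshold 46.4% of all genes tested were called for age in SOC and 46.5% for age in brain. The shares were 41.1% for SOC against brain at P4, 53.8% at P25 and 28.2% for the difference of age changes. Counts of members near these shares say nothing particular about a list. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a comparison, and again with a correlation estimated from the residuals.

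The genes named were, per direction, the 8 with the largest change among called genes with an official symbol, at least 2-fold changed, above background in both groups and without overlap between the groups' samples (6 for the difference of age changes, with no condition on overlap). To these were added, per direction, the 2 brightest genes not above background on any array of the other group, and from each list up to 4 called members with the largest change and up to 2 that were not called. A gene not above background in 1 group has a bound in place of a fold: the mean of the brighter group against the mean, over the dim group, of the higher of the dim probe's value and the lowest signal among probes above background on each array. Bounds that involve SOC remain open to dye bias, since its groups held the dyes unevenly, while each brain group held 3 samples of each dye. Some genes that this rule names are not reported here.

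The model was tested on simulated values for 28279 genes per comparison. It recovered 90%, 88%, 76%, 90% and 80% of genes changed 1.5-fold for the age change in SOC, the age change in brain, SOC against brain at P4, the same at P25 and the difference of age changes, and 100%, 98%, 100%, 100% and 88% of those changed 2-fold. False calls numbered between 12 and 16. Each of these shares rests on 50 simulated genes. The simulated shifted list was called in every comparison, with between 0 and 2 of the 31 other lists. The simulated genes varied independently of each other, so this cannot show how often camera calls lists of correlated genes by error. Alternatives covered the background correction, normalization, the authors' deposited values, the filter, the probe of a gene, the dye term, the block of linked samples, single hybridisations, the slide as a fixed term, within-array log ratios, fewer groups in the fit, the replicate number as a block, each replicate left out in turn (with the correlation of the full fit) and other thresholds. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.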

Results

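The series compared gene expression in the rat superior olivary complex, a group of auditory brainstem nuclei where input from both ears first converges, with that in whole brain, before hearing begins (P4) and when it is established (P25). Single-channel log2 intensities were obtained for 6 SOC samples at P4, 9 at P25, 6 brain samples at P4, 6 at P25 and 1 SOC sample at P0. Between 52.4% (brain P25 replicate 6) and 91.6% (SOC P4 replicate 1) of the probes were above background. The latter share came mainly from the sample's array on slide 1 (91.4%), and its other array gave 72.2%. Correlations across genes ranged from 0.967 to 0.997 within groups and from 0.901 to 0.970 between groups. The first principal component held 47.2% of the variance and the second 23.4%. On the second, brain replicates 5 and 6 lay apart from the other brain samples of their age, at -5.37 and -5.40 at P4 (others 10.2 to 15.3) and at -64.7 and -67.0 at P25 (others -57.5 to -44.9). These 4 samples had been hybridised on slides 10 and 11.

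The first comparison asked which genes change in the SOC between P4 (n = 6) and P25 (n = 9). Transcripts of myelin-forming oligodendrocytes led the increases. Opalin, a membrane protein of these cells, rose 90.9-fold (log2 change 6.51 ± 0.20, limma adjusted p = 5.34e-19), from a log2 intensity of 7.31 ± 0.66 to 13.89 ± 0.24, with SOC P25 replicate 9 apart from the others at 13.33. SOC P4 replicate 1 was at 8.50 and the other P4 samples between 6.55 and 7.39. On 1 of the 2 arrays of SOC P4 replicate 1, that on slide 1, the age difference was compressed, as described under the other observations. The iron carrier transferrin (Tf) rose 67.5-fold (6.08 ± 0.20), the nodal link protein Hapln2 59.7-fold (5.90 ± 0.33) and the myelin surface protein Mog 48.4-fold (5.60 ± 0.23), with SOC P25 replicate 7 apart at 15.85 after removal of the dye term. Genes of neuronal differentiation were among the leading decreases. Dcx, a microtubule-binding protein of migrating neurons, fell 9.23-fold (-3.21 ± 0.13, adjusted p = 7.61e-17), and the growth cone protein Dpysl3 fell 8.60-fold (-3.10 ± 0.23).

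The other leading increases were those of Mal (44.1-fold), the lipid carrier Apod (43-fold), the protease Klk6 (25.6-fold) and the phosphatase inhibitor Ppp1r14a (24.7-fold). The other leading decreases were those of the crystallin Crygn (9.97-fold), Cdhr1 (9.78-fold), the radial glia lipid carrier Fabp7 (7.93-fold), Ly6h (7.91-fold), Cpne5 (7.14-fold) and the synaptic kinase anchor Akap5 (6.83-fold). The Opalin probe lay on chromosome 1 from 246234694 to 246234753, the Mog probe on chromosome 20 from 1611776 to 1611835 and the Dcx probe on chromosome X from 34672024 to 34672079 of rn4. Pls1, a protein that bundles actin, was not above background on any P4 array and was at least 1.53-fold higher at P25 (adjusted p = 4.51e-06), and a gene model without an established name went at least 1.36-fold the other way (adjusted p = 8.54e-05). For 2 further transcripts of this kind only an accession is known, with bounds of 2.19-fold higher and 1.33-fold lower.

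In the mature oligodendrocyte and myelin list all 17 measured members rose (17 adjusted over the list alone), with a median log2 change of 3.74 (camera adjusted p = 4.54e-46). Mbp, the basic protein of myelin, rose by 4.36 ± 0.28. Of the 20 measured genes of cholesterol synthesis, 19 rose (19 adjusted over the list alone), with a median of 0.79 (adjusted p = 3.37e-12). Cyp51 rose by 1.82 ± 0.09, Sc5d by 1.59 ± 0.07 and Msmo1 by 1.53 ± 0.07, all enzymes of the late pathway, while the regulator Srebf2 was at -0.05 ± 0.14. Cell division genes fell in 25 of 26 cases (26 adjusted over the list alone), with a median of -1.12 (adjusted p = 3.21e-13), among them the mitotic kinase Cdk1 at -2.61 ± 0.22 and the topoisomerase Top2a at -1.69 ± 0.11. Immature neuron genes fell in 15 of 17 cases and 1 rose (16 and 1 adjusted over the list alone), with a median of -1.32 (adjusted p = 3.37e-12).

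Of 13 microglia genes 12 rose (12 adjusted over the list alone, median 0.61, camera adjusted p = 7.97e-08), led by the protease Ctss at 2.65 ± 0.08. Of 13 astrocyte genes 8 rose and 1 fell, with the same counts adjusted over the list alone (median 0.64, adjusted p = 0.00589), and the glutamate transporter Slc1a2 changed by 2.08 ± 0.13. Of 14 endothelial and pericyte genes 9 rose (9 adjusted over the list alone, median 0.53, adjusted p = 1.86e-05), led by the transporter Slco1a4 at 3.35 ± 0.15. Oligodendrocyte precursor genes rose in 3 of 9 cases and 3 fell, and 3 and 4 adjusted over the list alone, and the list was not called (median -0.05, mean 0.14, test upward, adjusted p = 0.968). In the chloride and bicarbonate list 9 of 21 rose and 3 fell, as they did adjusted over the list alone (median 0.22, adjusted p = 0.000127). The chloride importer Slc12a2 rose by 2.65 ± 0.08 and the carbonic anhydrase Car2 by 2.47 ± 0.08.

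Channel and receptor lists of neurons held members that changed strongly in both directions. Of 24 sodium and calcium channel genes 16 fell and 3 rose (16 and 4 adjusted over the list alone, median -0.58, camera adjusted p = 1.62e-06). The beta subunit Scn3b fell by 2.56 ± 0.13 and the embryonic channel Scn3a by 2.38 ± 0.10, whereas Scn4b, the subunit of resurgent sodium current, rose by 3.18 ± 0.13. Of 28 glutamate receptor and transporter genes 21 fell and 2 rose, with the same counts adjusted over the list alone (median -0.47, adjusted p = 0.000578; adjusted p = 0.166 with an estimated correlation). Grik1 fell by 1.70 ± 0.11 and Gria2 by 1.21 ± 0.09, and the NMDA receptor subunit Grin2c rose by 2.88 ± 0.20. The potassium and HCN channel list was not called (median 0.01, camera adjusted p = 0.201). Over all alternatives its camera adjusted p ran from 0.0332 to 0.471, so not every alternative left it uncalled. Of its genes 11 of 34 rose and 11 fell (12 and 11 adjusted over the list alone), among them Hcn2 at 2.57 ± 0.10 and Kcna1 at 2.41 ± 0.12. The calcium buffer Pvalb rose by 4.08 ± 0.15 in a list of 21 calcium-binding proteins of which 6 rose and 11 fell, also adjusted over the list alone (median -0.30, mean 0.05, test upward, adjusted p = 0.765).

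Other lists were called downward. Of 31 axon guidance genes 20 fell and 3 rose, the same adjusted over the list alone (median -0.43, camera adjusted p = 0.00293; adjusted p = 0.293 with an estimated correlation), and the guidance receptor Robo2 fell by 2.31 ± 0.08. Of 16 brainstem transcription factors 10 fell, the same adjusted over the list alone (median -0.30, adjusted p = 0.00143), with Nkx6-1 at -1.52 ± 0.09. Monoamine and motor neuron genes fell in 11 of 15 cases and 1 rose, the same adjusted over the list alone (median -0.57, adjusted p = 0.00632; adjusted p = 0.091 with an estimated correlation). The serotonin transporter Slc6a4 fell by 1.34 ± 0.12. The ion pump and energy list was called upward: 16 of 37 rose and 8 fell, and 16 and 9 adjusted over the list alone (median 0.18, adjusted p = 0.0191). That call was lost at adjusted p = 0.293 with an estimated correlation, at 0.0507 with slide as a block and at 0.0551 without the slide 1 array shared by SOC P4 replicate 1 and SOC P25 replicate 2.

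Hereditary deafness, glycinergic, GABA, perineuronal net and red blood cell lists were not called in SOC with age. Of 33 hereditary deafness genes 11 rose and 10 fell, the same adjusted over the list alone (median -0.00, mean 0.11, test upward, camera adjusted p = 0.673), and the collagen Col11a2 rose by 2.78 ± 0.17. Of 11 glycinergic genes 4 rose and 4 fell, the same adjusted over the list alone (median -0.04, adjusted p = 0.673). The fetal glycine receptor subunit Glra2 fell by 2.19 ± 0.12, while the adult subunit Glra1 rose by 0.71 ± 0.08. Of 19 GABA genes 3 rose and 9 fell, the same adjusted over the list alone (median -0.19, adjusted p = 0.0654). The GABA list was called downward without brain P25 replicate 6 (adjusted p = 0.0407), without brain replicates 5 and 6 of both ages (0.0245) and with slide as a fixed term (0.0429), with a range of 0.00994 to 0.287 over all alternatives. Perineuronal net matrix genes rose in 5 of 15 cases and 3 fell, the same adjusted over the list alone (median 0.24, adjusted p = 0.49), with tenascin C (Tnc) at -2.73 ± 0.14 and aggrecan (Acan) at 0.81 ± 0.09. Red blood cell genes rose in 4 of 7 cases, the same adjusted over the list alone (median 0.21, adjusted p = 0.213).

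By the limma fit 1086 genes were at least 2-fold higher and 978 at least 2-fold lower at P25. Values of the 15 samples did not overlap between ages for 1997 of these 2064 genes. Chance gives 0.04% of unselected genes, and here as in the later comparisons the genes had been selected on the same samples. With slide as a fixed term the counts were 1074 and 975. Within each of the 7 slides that held both ages at least 99.5% of the 2064 genes changed in the same direction, and all 14 called lists kept the sign of their median. Genes and lists had been called on these same arrays. Agreement within slides, here and in the later comparisons, was therefore largely fixed in advance and is no independent check. On slide 1 the median gene changed by 0.598 of its fitted change. With the authors' deposited values 40.1% of the changed genes were higher, against 52.6% here.

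The second comparison asked the same of whole brain (P4, n = 6; P25, n = 6). Myelin genes again led the increases. Opalin rose 50.3-fold (5.65 ± 0.21, limma adjusted p = 8.17e-18), with brain P25 replicate 5 apart from the others at 13.24, and Mog rose 38.9-fold (5.28 ± 0.23). Pvalb, the calcium buffer of fast-spiking neurons, rose 29.8-fold (4.90 ± 0.15, adjusted p = 3.88e-19), from a log2 intensity of 8.12 ± 0.46 to 13.04 ± 0.15. Dcx fell 14.5-fold (-3.86 ± 0.13) and Dpysl3 12.9-fold (-3.69 ± 0.24). Gpc2, a proteoglycan of growing axons, changed by -3.59 ± 0.24. Cd24, a surface protein of young neurons, fell 7.34-fold (-2.88 ± 0.11).

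Hapln2 (21.2-fold higher), Mobp (20.4-fold) and Mbp (4.27 ± 0.29) followed among the increases, with Mal at 4.59 ± 0.26, all genes of myelin or its nodes. Among the decreases were Igfbpl1 (8.39-fold lower), Pafah1b3 (8.31-fold), Cdk1 (7.62-fold) and the transcription factor Sox4 (6.57-fold). Chi3l1, a chitinase-like protein of astrocytes, was not above background on any P4 array and was at least 2.35-fold higher at P25 (adjusted p = 9.06e-12). For 3 other transcripts of this kind only an accession is known, with bounds of 3.00-fold higher, 2.15-fold lower and 2.02-fold lower.

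All 17 measured myelin genes rose (17 adjusted over the list alone, median 2.6, camera adjusted p = 1.1e-27), all 26 cell division genes fell (26 adjusted over the list alone, median -1.43, adjusted p = 2.8e-23) and 16 of 17 immature neuron genes fell (16 adjusted over the list alone, median -1.54, adjusted p = 4.83e-25). Of 15 cerebellum genes 12 rose and 1 fell, the same adjusted over the list alone (median 2.01, adjusted p = 3.25e-22). The granule cell GABA receptor subunit Gabra6 changed by 4.08 ± 0.16, the Purkinje cell gene Pcp2 by 2.86 ± 0.17 and the calcium release channel Itpr1 by 2.96 ± 0.12. Astrocyte genes rose in 10 of 13 cases and 1 fell, the same adjusted over the list alone (median 1.06, adjusted p = 5.25e-07).

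Calcium-binding proteins rose in 15 of 21 cases (15 adjusted over the list alone, median 0.87, camera adjusted p = 3.55e-08). Potassium and HCN channels rose in 19 of 34 cases with 4 falling (19 and 4 adjusted over the list alone, median 0.62, adjusted p = 3.55e-08), as did 2-pore and inward-rectifier potassium channels in 18 of 25 with 2 falling (18 and 2 adjusted over the list alone, median 0.45, adjusted p = 4.52e-05). Kcna1, a channel of axons and their terminals, rose by 3.52 ± 0.13 and the inward rectifier Kcnj12 by 2.35 ± 0.15. GABA genes rose in 10 of 19 cases and 3 fell, the same adjusted over the list alone (median 0.57, adjusted p = 1.09e-06), with the extrasynaptic receptor subunit Gabrd at 3.71 ± 0.09. The GABA median per sample, after removal of the dye term, was 0.13 and 0.12 in brain P25 replicates 5 and 6 and between 0.52 and 0.72 in the other 4, and without replicates 5 and 6 of both ages the list changed by 0.53. Sodium and calcium channel genes rose in 11 of 24 cases and 3 fell, the same adjusted over the list alone (median 0.24, adjusted p = 0.00511), with Scn4b at 4.08 ± 0.13. Immediate early and heat shock genes rose in 14 of 18 cases (14 adjusted over the list alone, median 0.65, adjusted p = 3.69e-09), with Egr4 at 3.13 ± 0.14, Egr1 at 3.06 ± 0.18 and Arc at 2.70 ± 0.13, all transcribed within minutes of neuronal activity. Neuropeptides rose in 12 of 19 cases and 1 fell (13 and 1 adjusted over the list alone, median 0.70, adjusted p = 0.000499), and ion pump and energy genes rose in 26 of 37 with 2 falling, the same adjusted over the list alone (median 0.53, adjusted p = 3.12e-10).

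Synaptic vesicle genes rose in 21 of 36 cases and 4 fell, and 21 and 5 adjusted over the list alone (median 0.43, camera adjusted p = 0.000287; adjusted p = 0.224 with an estimated correlation). Neurofilament genes rose in 6 of 13 cases and 2 fell (median 0.36, adjusted p = 0.32) and glycinergic genes rose in 3 of 11 and 3 fell (median -0.06, adjusted p = 0.45), the same adjusted over each list alone, and neither list was called. Among the vesicle genes the release protein Snap25 rose by 2.36 ± 0.09. Per sample the vesicle median was 0.00 and 0.06 in brain P25 replicates 5 and 6 and between 0.57 and 0.70 in the other 4, and it changed by 0.58 without replicates 5 and 6 of both ages. Glutamate genes rose in 13 of 28 cases and 6 fell, the same adjusted over the list alone (median 0.12, adjusted p = 0.00127; adjusted p = 0.145 with an estimated correlation), with Grin2c at 4.21 ± 0.21. The glutamate median was 0.19 without brain P25 replicate 6 and 0.19 without replicates 5 and 6 of both ages. Cholesterol synthesis genes fell in 11 of 20 cases and 3 rose, and 12 and 3 adjusted over the list alone (median -0.30, adjusted p = 0.0393; adjusted p = 0.145 with an estimated correlation). Dhcr7, the last enzyme of the pathway, was at -0.95 ± 0.10 and Fdps at -0.84 ± 0.13. That call was also lost without brain P4 replicate 4 (adjusted p = 0.0532), brain P25 replicate 5 (0.0532) or brain P25 replicate 6 (0.0568).

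Axon guidance genes fell in 18 of 31 cases and 4 rose, and 20 and 4 adjusted over the list alone (median -0.39, camera adjusted p = 0.0162; adjusted p = 0.331 with an estimated correlation). Choroid plexus genes fell in 6 of 10 cases, the same adjusted over the list alone (median -0.32, adjusted p = 0.0162; adjusted p = 0.0999 with an estimated correlation), with Otx2 at -1.33 ± 0.10. Meninges and fibroblast genes fell in 8 of 11 cases, the same adjusted over the list alone, and the list was not called (median -0.61, adjusted p = 0.057; adjusted p = 0.421 with an estimated correlation). It was called without SOC P4 replicate 1 (adjusted p = 0.00839), 4 (0.0247) or 5 (0.0496), brain P4 replicate 4 (0.0408) or 6 (0.0468) or brain P25 replicate 2 (0.0482), and without brain replicates 5 and 6 of both ages (0.0437), with a range of 6.92e-06 to 0.421 over all alternatives. Red blood cell genes rose in 4 of 7 cases, the same adjusted over the list alone, and were not called (median 0.42, adjusted p = 0.212), with brain P25 replicate 5 apart from the others. Hox genes fell in 6 of 12 cases and 1 rose, the same adjusted over the list alone (median -0.16, adjusted p = 0.0229; adjusted p = 0.0887 with an estimated correlation), with Hoxa5 at -1.73 ± 0.12 and a list median of -0.26 without brain replicates 5 and 6 of both ages. Chloride and bicarbonate genes rose in 11 of 21 cases and 2 fell, the same adjusted over the list alone (median 0.25, adjusted p = 0.00017). The chloride exporter of neurons, Slc12a5, rose by 1.40 ± 0.12.

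In whole brain 1071 genes were at least 2-fold higher and 705 at least 2-fold lower at P25 by limma, 1696 of the 1776 with no overlap between the 12 samples (chance, 0.216% of unselected genes). The counts were 1060 and 715 with slide as a fixed term. Within each of the 4 slides with both ages at least 99.9% of the 1776 genes and all 20 called lists went the same way, though they had been called on these same arrays.

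**Figure D1:**
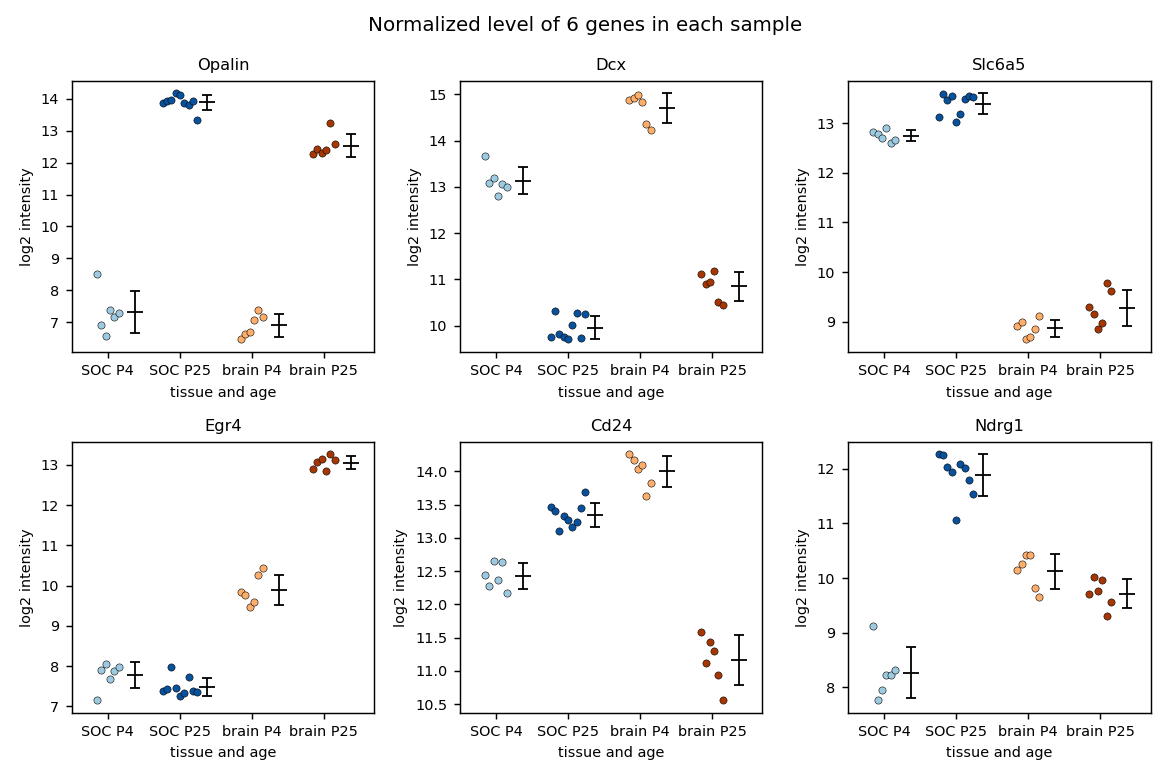
Normalized log2 intensity (vertical axis) of Opalin, Dcx, Slc6a5, Egr4, Cd24 and Ndrg1 in each sample of SOC P4 (n = 6), SOC P25 (n = 9), brain P4 (n = 6) and brain P25 (n = 6), with points for samples and bars for the mean ± SD. Opalin is high at P25 in both tissues, Slc6a5 in SOC at both ages, and Egr4 reaches 13.05 ± 0.16 in brain at P25 alone.

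The third comparison set SOC (n = 6) against whole brain (n = 6) at P4. Slc6a5, the neuronal glycine transporter, was 15.2-fold higher in SOC (3.92 ± 0.12, limma adjusted p = 4.27e-19), at 12.75 ± 0.12 against 8.87 ± 0.17. The heavy neurofilament gene Nefh was 6.24-fold higher (2.64 ± 0.22) and the bicarbonate transporter Slc4a4 6.87-fold (2.78 ± 0.31). Genes typical of tissues outside the brainstem were lower. Ttr, the thyroid hormone carrier of choroid plexus, was 56-fold lower (-5.81 ± 0.33), the transcription factor Otx2 25.7-fold (-4.68 ± 0.11) and the hypothalamic peptide Pmch 17.8-fold (-4.15 ± 0.08). SOC tissue had been sliced and extracted differently from brain, so tissue and handling cannot be told apart here or at P25.

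Also higher in SOC at P4 were Lamp5 (7.66-fold higher), the lipase Pnlip (6.49-fold), Lyzl4 (5.77-fold), Pla2g7 (5.69-fold) and the oligodendrocyte phosphodiesterase Enpp6 (5.30-fold). Lower in SOC were Hoxa5 (13.4-fold), the prostaglandin D synthase Ptgds (11.2-fold), Igfbpl1 (11.2-fold), the guanine deaminase Gda (-3.48 ± 0.14) and the peptide Cck (-3.47 ± 0.18). The Slc6a5 probe lay on chromosome 1 from 99792981 to 99793040 and the Ttr probe on chromosome 18 from 12407757 to 12407816 of rn4. For 3 transcripts known only by an accession and not above background on any array of 1 tissue, the bounds were 1.68-fold and 1.57-fold higher and 2.84-fold lower.

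Forebrain genes were lower in 14 of 16 cases (15 adjusted over the list alone, median -1.49, camera adjusted p = 2.39e-34), with the interneuron factor Dlx5 at -4.03 ± 0.13 and the cortical factor Neurod2 at -3.11 ± 0.21. Choroid plexus genes were lower in 9 of 10 cases (9 adjusted over the list alone, median -0.95, adjusted p = 8.52e-23). So were meninges and fibroblast genes in 10 of 11 (10 adjusted over the list alone, median -1.64, adjusted p = 2.26e-08). Neuropeptides were lower in 12 of 19 cases with 4 higher (13 and 4 adjusted over the list alone, median -0.96, adjusted p = 1.93e-18). Immature neuron genes were lower in 11 of 17 cases (11 adjusted over the list alone, median -0.61, adjusted p = 1.51e-07). The collagen Col1a2 was at -2.57 ± 0.22.

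Glycinergic genes were higher in 7 of 11 cases and 1 was lower, the same adjusted over the list alone (median 0.52, camera adjusted p = 3.97e-05), among them the receptor subunits Glrb at 0.97 ± 0.17 and Glra1 at 0.94 ± 0.09. Monoamine and motor neuron genes were higher in 12 of 15 cases and 1 lower, the same adjusted over the list alone (median 0.77, adjusted p = 1.36e-06), led by Tph2, which makes serotonin, at 2.21 ± 0.15. Brainstem transcription factors were higher in 9 of 16 cases and 2 lower, the same adjusted over the list alone (median 0.28, adjusted p = 4.13e-06), led by Nkx6-1 at 2.21 ± 0.10. Myelin genes were higher in 15 of 17 cases (15 adjusted over the list alone, median 1.09, adjusted p = 1.94e-07). Oligodendrocyte precursor genes were higher in 6 of 9 cases with 1 lower (6 and 1 adjusted over the list alone, median 0.40, adjusted p = 0.000104), and astrocyte genes in 11 of 13 (11 adjusted over the list alone, median 0.75, adjusted p = 1.77e-05). Ion pump and energy genes were higher in 25 of 37 cases with 2 lower (25 and 2 adjusted over the list alone, median 0.47, adjusted p = 9.68e-06). Mbp was at 2.39 ± 0.31.

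The remaining called lists lost their call with an estimated correlation. Axon guidance genes were lower in 16 of 31 cases and 3 were higher, and 17 and 3 adjusted over the list alone (median -0.21, camera adjusted p = 0.0234; adjusted p = 0.374 with an estimated correlation), with a median of -0.32 without brain replicates 5 and 6 of both ages. Cerebellum genes were lower in 9 of 15 cases and 4 were higher, the same adjusted over the list alone (median -0.52, adjusted p = 0.0307; adjusted p = 0.0801 with an estimated correlation). Immediate early and heat shock genes were lower in 11 of 18 cases and 3 were higher, the same adjusted over the list alone (median -0.31, adjusted p = 0.0239; adjusted p = 0.143 with an estimated correlation). Microglia genes were higher in 7 of 13 cases, the same adjusted over the list alone (median 0.30, adjusted p = 0.0107; adjusted p = 0.14 with an estimated correlation). Neurofilament genes were higher in 8 of 13 cases and 3 were lower, the same adjusted over the list alone (median 0.63, adjusted p = 0.0307; adjusted p = 0.168 with an estimated correlation). With slide as a block, axon guidance (adjusted p = 0.0694) and immediate early genes (0.0617) were not called.

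Of 12 Hox genes 5 were lower and 2 higher, the same adjusted over the list alone (median -0.06, camera adjusted p = 0.0281; adjusted p = 0.0966 with an estimated correlation). Hoxa2, which patterns the anterior hindbrain, was higher by 2.03 ± 0.12, and Hoxa5, expressed farther back, was at -3.75 ± 0.13. The list's median lay between -0.38 and 0.18 (detection at 13 SDs) over the alternatives and was -0.09 without brain replicates 5 and 6 of both ages, and its call was lost without SOC P4 replicate 1 (adjusted p = 0.0536). Synaptic vesicle genes were higher in 15 of 36 cases and 5 lower, and 15 and 6 adjusted over the list alone (median 0.20, adjusted p = 0.0439; adjusted p = 0.537 with an estimated correlation). The release sensor Syt2 was at 1.60 ± 0.10. The vesicle call was lost without SOC P4 replicate 4 (adjusted p = 0.0644) or 5 (0.0638), without brain P4 replicate 5 (0.0683) or 6 (0.0827), and without brain replicates 5 and 6 of both ages (0.163).

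At P4, 523 genes were at least 2-fold higher and 690 at least 2-fold lower in SOC by limma, 1165 of the 1213 with no overlap between the 12 samples (chance, 0.216% of unselected genes). With slide as a fixed term the counts were 547 and 602. Within each of the 3 slides with both tissues at this age at least 98.8% of the genes went the same way, and 16 of 19 called lists kept the sign of their median, with exceptions in axon guidance, Hox and microglia genes. The median log2 difference of all genes was 0.16 with the deposited values and 0.01 here, and with those values 61.0% of changed genes were higher, against 43.1% here.

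The fourth comparison repeated this at P25 (SOC, n = 9; brain, n = 6). Slc6a5 was 18.3-fold higher in SOC (4.19 ± 0.10, limma adjusted p = 7.45e-22). The secreted matrix protein osteopontin (Spp1) was 10.8-fold higher (3.43 ± 0.14), Apod 10.8-fold (3.43 ± 0.12) and Tf 9.83-fold (3.30 ± 0.19). Itpka, a kinase of dendritic spines, was 60.9-fold lower (-5.93 ± 0.17), Egr4 45.6-fold (-5.51 ± 0.13, adjusted p = 1.46e-22) and Neurod1, a transcription factor of granule neurons, 44.2-fold (-5.46 ± 0.15). Cck was 29.3-fold lower and Pmch 28.6-fold.

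Also higher in SOC were the glucagon receptor Gcgr (9.41-fold), the crystallin Cryba2 (9.37-fold), the galactolipid enzyme Ugt8 (8.1-fold) and the 2-pore potassium channel Kcnk15 (7.82-fold). Lower were Gda (-4.81 ± 0.12), Syne1 (26.3-fold) and Kcnv1 (26.0-fold), a silent potassium channel subunit. The Gcgr probe lay on chromosome 10 from 109929476 to 109929535 and the Egr4 probe on chromosome 4 from 119765289 to 119765348 of rn4. The choroid plexus channel Kcnj13 and the dopamine transporter Slc6a3 were not above background on any SOC P25 array and were at least 3.7-fold and 2.26-fold lower there (adjusted p = 2.5e-17 and 1.57e-12).

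All 20 measured cholesterol synthesis genes were higher in SOC at P25 (20 adjusted over the list alone, median 1.05, camera adjusted p = 2.8e-18), with Cyp51 at 2.44 ± 0.09 and the squalene epoxidase Sqle at 2.00 ± 0.08. All 17 myelin genes (17 adjusted over the list alone, median 1.97, adjusted p = 1.42e-13) and all 13 microglia genes (13 adjusted over the list alone, median 1.04, adjusted p = 2.13e-08) were higher too, led by Ugt8 at 3.02 ± 0.15 and the purine receptor P2ry12 at 1.57 ± 0.12. Glycinergic genes were higher in 7 of 11 cases and 2 lower, the same adjusted over the list alone (median 0.34, adjusted p = 0.000886), and oligodendrocyte precursor genes in 6 of 9 with 1 lower, the same adjusted over the list alone (median 0.43, adjusted p = 0.0124). The precursor call was lost with the deposited values (adjusted p = 0.0619; 0.00103 to 0.0619 over all alternatives).

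Forebrain genes were lower in 14 of 16 cases (14 adjusted over the list alone, median -2.53, camera adjusted p = 1.93e-32). Neuropeptides were lower in 15 of 19 cases with 2 higher (15 and 2 adjusted over the list alone, median -1.89, adjusted p = 1.05e-31). Cerebellum genes were lower in 14 of 15 cases with 1 higher (14 and 1 adjusted over the list alone, median -2.48, adjusted p = 9.09e-25), as were choroid plexus genes in 8 of 10 with 1 higher (8 and 1 adjusted over the list alone, median -0.50, adjusted p = 2.97e-07). Sodium and calcium channel genes were lower in 18 of 24 cases and 5 higher, the same adjusted over the list alone (median -0.51, adjusted p = 2.67e-11), with the accessory subunits Cacna2d1 at -3.76 ± 0.08 and Cacnb3 at -3.45 ± 0.06. GABA genes were lower in 14 of 19 cases and 3 higher (14 and 4 adjusted over the list alone, median -0.67, adjusted p = 1.91e-09). Glutamate genes were lower in 18 of 28 cases with 2 higher, the same adjusted over the list alone (median -0.78, adjusted p = 1.53e-08). Immediate early genes were lower in 12 of 18 cases with 3 higher (13 and 3 adjusted over the list alone, median -0.57, adjusted p = 6.09e-09), with Egr1 at -4.43 ± 0.17 and Arc at -2.94 ± 0.12. Calcium-binding proteins were lower in 11 of 21 cases and 5 higher, the same adjusted over the list alone (median -0.21, adjusted p = 0.0039), and 2-pore and inward-rectifier potassium channels in 15 of 25 with 7 higher (16 and 7 adjusted over the list alone, median -0.27, adjusted p = 0.000383).

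A further 5 lists were called and lost their call with an estimated correlation. Axon guidance genes were lower in 16 of 31 cases and 2 higher, the same adjusted over the list alone (median -0.24, camera adjusted p = 0.0124; adjusted p = 0.288 with an estimated correlation). Synaptic vesicle genes were lower in 21 of 36 cases and 6 higher, and 23 and 6 adjusted over the list alone (median -0.32, adjusted p = 0.000513; adjusted p = 0.237 with an estimated correlation). Their median was -0.49 without brain replicates 5 and 6 of both ages, and those 2 samples at P25 (0.00 and 0.06 per sample, after removal of the dye term) lay near the SOC samples (-0.13 to 0.04). Potassium and HCN channel genes were lower in 14 of 34 cases and 9 higher, the same adjusted over the list alone (median -0.13, adjusted p = 0.0207; adjusted p = 0.114 with an estimated correlation), with a median of -0.24 without those 4 brain samples. Meninges and fibroblast genes were lower in 8 of 11 cases and 1 higher, the same adjusted over the list alone (median -0.84, adjusted p = 0.0389; adjusted p = 0.379 with an estimated correlation). Their call was lost without SOC P25 replicate 2 (adjusted p = 0.0503), without brain P25 replicate 3 (0.051) and without brain replicates 5 and 6 of both ages (0.077). Monoamine and motor neuron genes were higher in 8 of 15 cases and 1 lower, the same adjusted over the list alone (median 0.20, adjusted p = 0.0366; adjusted p = 0.154 with an estimated correlation). This call was lost without those 4 brain samples (0.0648).

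Neurofilament genes were higher in 6 of 13 cases and 2 lower, the same adjusted over the list alone, and the list was not called (median -0.06, mean 0.21, test upward, camera adjusted p = 0.592). Nefh was at 2.26 ± 0.19. The list of perineuronal net matrix was not called either (camera adjusted p = 0.0718), with Acan at 1.02 ± 0.08. Of its 15 genes 8 were higher and 1 lower, the same adjusted over the list alone. Its camera adjusted p ran from 0.0102 to 0.154 over all alternatives, so some of them called it. Its median per sample was -0.0081 in SOC P25 replicate 5 and between 0.49 and 0.73 in the other SOC P25 samples, after removal of the dye term.

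At P25, 879 genes were at least 2-fold higher and 1349 at least 2-fold lower in SOC by limma, 2085 of the 2228 with no overlap between the 15 samples (chance, 0.04% of unselected genes). With slide as a fixed term the counts were 900 and 1213, and the meninges (adjusted p = 0.0554) and potassium and HCN channel lists (0.108) were not called. Within each of the 4 slides with both tissues at least 98.8% of the genes went the same way, and 18 of 20 called lists kept their sign, with exceptions in synaptic vesicle and potassium and HCN channel genes. The median log2 difference of all genes was 0.11 with the deposited values and 0.02 here.

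The last comparison asked whether the age change differed between SOC (P4, n = 6; P25, n = 9) and brain (P4, n = 6; P25, n = 6), by subtracting the brain's change from that of the SOC. Ndrg1, a stress-responsive gene of myelinating glia, led the positive differences (3.95 ± 0.23, limma adjusted p = 6.16e-13): its log2 intensity was 8.27 ± 0.47 and 11.89 ± 0.38 in SOC at P4 and P25, and 10.12 ± 0.32 and 9.72 ± 0.26 in brain. For Ndrg1 SOC P4 replicate 1 was at 9.13 and the other SOC P4 samples between 7.76 and 8.32. Cd24 differed by 3.87 ± 0.16, from 12.42 ± 0.19 to 13.35 ± 0.18 in SOC and from 14.00 ± 0.23 to 11.16 ± 0.37 in brain. The trefoil peptide Tff3 led the negative differences (-4.39 ± 0.25), from 8.30 ± 0.45 to 11.86 ± 0.19 in brain and from 8.23 ± 0.40 to 7.31 ± 0.33 in SOC. The adrenergic receptor Adra1d differed by -4.12 ± 0.28 and Akap5 by -3.93 ± 0.30.

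Positive differences followed for Ptgds (3.30 ± 0.23), the ATP-gated channel subunit P2rx6 (2.601 ± 0.15), the G protein subunit Gng8 (2.54 ± 0.21) and the activin subunit Inhbb (2.53 ± 0.16). Negative differences followed for Kcnv1 (-3.46 ± 0.16), Egr4 (-3.42 ± 0.19) and the Purkinje cell phosphatase inhibitor Ppp1r17 (-3.29 ± 0.13). The Ndrg1 probe lay on chromosome 7 from 104302898 to 104302957, the Cd24 probe on chromosome 20 from 47507471 to 47507530 and the Tff3 probe on chromosome 20 from 9469906 to 9469962 of rn4.

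Of the 20 cholesterol synthesis genes 18 changed more upward in SOC (18 adjusted over the list alone, median 1.25, camera adjusted p = 7.95e-27), led by Fdps at 1.89 ± 0.18, Lss at 1.82 ± 0.17 and Hmgcs1 at 1.80 ± 0.13. Differences were also positive for 9 of 17 myelin genes (10 adjusted over the list alone, median 0.76, adjusted p = 9.48e-05) and 11 of 13 microglia genes (12 adjusted over the list alone, median 0.58, adjusted p = 2.23e-05). The same held for 8 of 14 endothelial and pericyte genes (8 adjusted over the list alone, median 0.37, adjusted p = 0.00359) and for 7 of 10 choroid plexus genes with 1 negative (7 and 1 adjusted over the list alone, median 0.44, adjusted p = 0.0011). The choroid plexus list was not called with age in SOC (median -0.02, camera adjusted p = 0.793). Its positive difference thus reflects its fall in brain (median -0.32) and no rise in SOC. The differences were negative for 19 of 24 sodium and calcium channel genes (20 adjusted over the list alone, median -0.96, adjusted p = 4.45e-20), with Cacnb3, a subunit of calcium channels, at -2.39 ± 0.08 and Scn2a, a channel of axons, at -2.17 ± 0.17. They were negative likewise for 11 of 15 cerebellum genes with 1 positive, the same adjusted over the list alone (median -2.17, adjusted p = 2.31e-26).

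Differences were negative for 12 of 19 GABA genes (14 adjusted over the list alone, median -0.72, camera adjusted p = 5.81e-16) and 17 of 28 glutamate genes with 1 positive (19 and 1 adjusted over the list alone, median -1.04, adjusted p = 5.81e-16). Synaptic vesicle genes differed negatively in 24 of 36 cases (25 adjusted over the list alone, median -0.66, adjusted p = 2.07e-11). The release sensor Syt1 was at -2.65 ± 0.24 and the glutamate receptor Grm4 at -2.81 ± 0.13. Of 11 glycinergic genes 2 differed positively and 2 negatively, and 3 and 2 adjusted over the list alone, and the list was not called (median -0.03, test upward, adjusted p = 0.921). Differences were negative for 13 of 21 calcium-binding proteins (13 adjusted over the list alone, median -0.81, adjusted p = 8.28e-09). They were negative for 13 of 19 neuropeptides and positive for 3, the same adjusted over the list alone (median -0.92, adjusted p = 8.28e-09), with Vip at -2.78 ± 0.27. Of 18 immediate early genes 7 differed negatively (7 adjusted over the list alone, median -0.21, adjusted p = 1.33e-06).

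Among 2-pore and inward-rectifier potassium channels 14 of 25 differed negatively and 3 positively, and 15 and 4 adjusted over the list alone (median -0.49, camera adjusted p = 3.35e-06). Kcnj12 was at -2.92 ± 0.21 and Kcnk15 at 2.10 ± 0.23. Among potassium and HCN channels 15 of 34 differed negatively and 4 positively, and 16 and 4 adjusted over the list alone (median -0.27, adjusted p = 7.25e-06), with Hcn2 at 1.40 ± 0.15. Ion pump genes differed negatively in 14 of 37 cases and positively in 3, and 17 and 3 adjusted over the list alone (median -0.34, adjusted p = 2.44e-05). Astrocyte genes differed negatively in 7 of 13 cases and positively in 1, the same adjusted over the list alone (median -0.38, adjusted p = 0.0215). The astrocyte call was lost with the deposited values (adjusted p = 0.206; 6.73e-05 to 0.206 over all alternatives).

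The other 7 called lists lost their call with an estimated correlation. Immature neuron genes differed positively in 6 of 17 cases and negatively in 4, the same adjusted over the list alone (median 0.47, camera adjusted p = 0.000632; adjusted p = 0.136 with an estimated correlation). Forebrain genes differed positively in 5 of 16 cases and negatively in 7, and 6 and 7 adjusted over the list alone (median -0.33, adjusted p = 0.00986; adjusted p = 0.226 with an estimated correlation). The forebrain median was -0.20 and -0.18 without brain P4 replicates 5 and 6 in turn, and -0.19 without brain P25 replicate 3 or 4. Hox genes differed positively in 4 of 12 cases and negatively in 2, the same adjusted over the list alone (median 0.09, adjusted p = 0.0123; adjusted p = 0.0568 with an estimated correlation). The Hox median was 0.16 without brain replicates 5 and 6 of both ages and lay between 0.02 and 1.33 over all alternatives. Meninges and fibroblast genes differed positively in 7 of 11 cases, and 10 positively and 1 negatively adjusted over the list alone (median 0.90, adjusted p = 0.00311; adjusted p = 0.21 with an estimated correlation), with a median of 0.59 without SOC P4 replicate 1.

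Cell division genes differed positively in 8 of 26 cases, and in 9 adjusted over the list alone (median 0.25, camera adjusted p = 0.0117; adjusted p = 0.327 with an estimated correlation), a call lost without SOC P4 replicate 1 (median 0.16, adjusted p = 0.0534). The median was also 0.16 without the slide 1 array of that sample. Brainstem transcription factors differed negatively in 7 of 16 cases, and in 7 with 1 positive adjusted over the list alone (median -0.23, adjusted p = 0.00986; adjusted p = 0.0655 with an estimated correlation). Monoamine and motor neuron genes differed negatively in 6 of 15 cases, the same adjusted over the list alone (median -0.20, adjusted p = 0.0311; adjusted p = 0.16 with an estimated correlation). The monoamine call was lost without SOC P4 replicate 1 (adjusted p = 0.051) or SOC P25 replicate 8 (0.0564). Without brain replicates 5 and 6 of both ages the brainstem (0.0702) and monoamine calls (0.19) were lost.

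By limma 457 genes had a positive and 833 a negative difference of at least 2-fold. The counts were 444 and 856 with slide as a fixed term, and all 24 lists were called in that fit too. Among genes changed at least 2-fold with age, 447 were higher and 361 lower in both tissues, where independent lists would share 41.1 and 24.4. The difference of the changes was itself called for 216 of the 447 and 133 of the 361. Another 28 genes fell in SOC and rose in brain, and 0 did the reverse at 2-fold. Across the 28279 genes, which are not independent replicates, the age changes of the 2 tissues correlated at Pearson's r = 0.647 (Spearman's rho = 0.589).

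**Figure D2:**
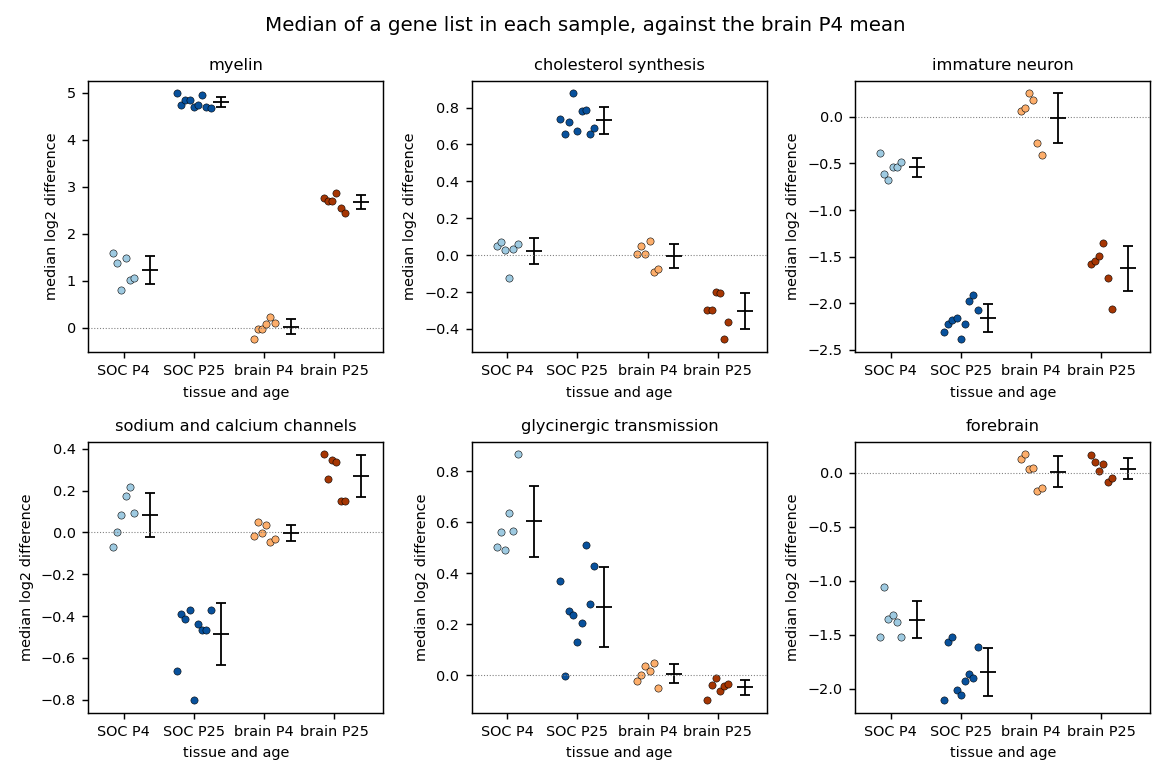
Median normalized log2 intensity of 6 gene lists in each sample after removal of the dye term, relative to the brain P4 mean (vertical axis, log2), for SOC P4 (n = 6), SOC P25 (n = 9), brain P4 (n = 6) and brain P25 (n = 6), with points for samples and bars for the mean ± SD. The cholesterol synthesis median was 0.73 ± 0.07 in SOC at P25 and -0.30 ± 0.10 in brain at P25, against 0.02 ± 0.07 in SOC at P4.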

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

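The tests of slides, normalization, the share of oligodendrocytes and dilution in this part were chosen only after the results were seen, while the tests on other splits of the samples were planned.

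The age change in SOC minus that in brain was positive for 457 and negative for 833 genes, by at least 2-fold in limma's test of the difference. The genes named for it were Ndrg1 (3.95), Cd24 (3.87), Ptgds (3.30), P2rx6 (2.601), Gng8 (2.545) and Inhbb (2.53), and Tff3 (-4.39), Adra1d (-4.115), Akap5 (-3.93), Kcnv1 (-3.46), Egr4 (-3.42) and Ppp1r17 (-3.29). By camera at the preset correlation 24 gene lists differed, 17 of them also with an estimated correlation. Cholesterol synthesis (median 1.25), meninges and fibroblast (0.90), mature oligodendrocyte and myelin (0.76), microglia (0.58), immature neuron (0.47), choroid plexus (0.44), endothelial cell and pericyte (0.37), cell division (0.25) and Hox genes (0.090) had positive medians. The cerebellum (-2.17), glutamate (-1.04), sodium and calcium channel (-0.96), neuropeptide (-0.92), calcium-binding (-0.81), GABA (-0.72) and synaptic vesicle lists (-0.66) had the lowest medians. Medians were also negative for 2-pore and inward-rectifier potassium channels (-0.49), astrocyte (-0.38), ion pump (-0.34), forebrain (-0.33), potassium and HCN channels (-0.27), brainstem transcription factors (-0.23), immediate early (-0.21) and monoamine and motor neuron genes (-0.20).

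Single samples stood apart from their group in 13 of 257 groups of values (5.06%), and chance alone gives about 1 in 20. These per-sample values had the fitted dye term removed, so they differ slightly from the plotted intensities of the genes. Mog was at 15.85 in SOC P25 replicate 7 (others 15.29 to 15.55). Opalin was at 13.38 in SOC P25 replicate 9 (others 13.8 to 14.2) and at 13.29 in brain P25 replicate 5 (others 12.31 to 12.58). In SOC P25 replicate 5 the list medians of perineuronal net matrix (-0.0081), ion pump (0.54) and monoamine and motor neuron genes (0.63, others 0.07 to 0.20) stood apart, and in SOC P25 replicate 4 that of potassium and HCN channels (-0.0395). In brain P4 replicate 6 the medians of GABA genes (-0.14), meninges and fibroblast genes (-0.19) and potassium and HCN channels (-0.066) stood apart. So did that of potassium and HCN channels in brain P25 replicate 6 (0.28), that of red blood cell genes in brain P25 replicate 5 (0.98, others 0.17 to 0.37) and that of cholesterol synthesis in SOC P4 replicate 4 (-0.12). No explanation of these samples was tested. The SOC sample from P0, which entered no comparison, had 70.0% of probes above background.

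Cholesterol synthesis genes rose with age in SOC and most fell in brain, with per-sample list medians of 0.02 ± 0.07 at P4 and 0.73 ± 0.07 at P25 in SOC, and of -0.00 ± 0.07 and -0.30 ± 0.10 in brain. Slide or scan batch was argued against by a difference of 1.16 on the 4 slides that held both tissues, with slide as a term, and normalization by a lowest difference of 1.22 over 4 other normalizations. For a higher share of oligodendrocytes alone, the prediction was a rise of this list in brain, where all 17 myelin genes rose. The per-sample cholesterol median in brain changed by -0.299 instead. In brain the camera call of the cholesterol list was weak (adjusted p = 0.0393, and 0.145 with an estimated correlation). Whole brain also mixes all cell types, and a fall in other cells could mask a gain in oligodendrocytes. The test therefore cannot exclude their share as the cause in SOC. At P25 the myelin list was also higher in SOC than in brain (median 1.97). Another candidate, not tested, is that sterol synthesis per glial cell or in neurons is higher in SOC than in brain at P25. The different handling of the tissues stays open for the difference between them.

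In SOC 6 neuronal lists (sodium and calcium channels, potassium and HCN channels, glutamate, glycinergic, synaptic vesicle and neurofilament genes) held 146 different genes, of which 31 rose and 76 fell with age, with a median log2 change of -0.27. Dilution of neuronal RNA by glial RNA alone would lower neuronal genes together. Of the 146, 14 rose at least 2-fold and 25 fell at least 2-fold, with changes from -2.56 to 3.18. The glutamate list also covers transporters, and the glutamate transporter Slc1a2 is given above among astrocyte genes. Some of the 14 may thus be glial, so their number alone does not exclude dilution. Normalization was argued against by the sodium and calcium channel list, whose highest median over 4 other normalizations was -0.61. Dilution may still add a part common to all members, and a change of the neurons themselves between the ages was not tested. By themselves only the sodium and calcium channel and the glutamate lists were called, the latter at adjusted p = 0.166 with an estimated correlation. Synaptic vesicle genes rose in 8 of 36 cases and 20 fell, and 8 and 21 adjusted over the list alone (median -0.28, adjusted p = 0.063). Their list was called downward without SOC P4 replicate 6 (adjusted p = 0.0471), brain P25 replicate 6 (0.0396) or brain replicates 5 and 6 of both ages (0.00865), with a range of 0.00195 to 0.601 over all alternatives.

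In every comparison only the real one of 100 splits of the samples (1 of 100) gave as many changed genes. For counts of genes this excludes only a chance division of samples whose groups do not differ. Other splits move the real difference into the residual, and they took no account of shared arrays or slides. The real and the highest other counts were 2064 and 1193 for the age change in SOC, 1776 and 1181 in brain, 1213 and 572 for the tissues at P4, 2228 and 1166 at P25, 1290 and 1 for the difference of age changes, and 808 and 0 for genes changed in both tissues. Chance could not be excluded for the number of lists called in 4 comparisons. As many lists were called in 16 of 100 splits for the age change in SOC (real 14, highest other 17), 13 in brain (20 and 23), 6 for the tissues at P4 (19 and 21) and 8 at P25 (20 and 23). For the difference of age changes only the real one gave as many lists, 1 of 100 splits (24 and 21). The splits for the difference exchanged ages within each tissue and so removed the age changes too. They cannot test the difference by itself. The other splits with the most genes or lists kept 10 of 12 samples in their own group in brain and between tissues at P4. For age in SOC and the tissues at P25 they kept 3 to 5 of 15, mostly an exchange of the 2 groups, so in all 4 comparisons they carried part of the real contrast. The number of lists called by camera in these 4 comparisons therefore says little by itself.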

How the results depend on the processing

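All alternatives were planned except 3 that were chosen after the data were seen: detection at 13 SDs of the negative controls, the fit without the slide 1 array of SOC P4 replicate 1 and SOC P25 replicate 2, and the fit without brain replicates 5 and 6 of both ages.

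Counts of genes changed at least 2-fold stayed within 1.5 times the reported count except in the cases given here. Without a minimum fold, a construction that can only add genes, 6316 genes rose and 6797 fell with age in SOC, 6627 and 6526 in brain, and 3688 and 4007 in both. In the same way 5939 were higher and 5687 lower in SOC at P4, 7984 and 7243 at P25, and the difference of age changes had 3892 and 4069. With the authors' deposited values 1671 genes fell in SOC, 1063 in brain and 631 in both, and 934 were higher in SOC at P4. The cause was not tested. All 2064 genes reported for SOC with age kept their direction with those values, and 1968 kept a 2-fold change.

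Over all alternatives with the 2-fold minimum, the deposited values included, 853 to 1386 genes were higher with age in SOC. In brain 947 to 1237 were higher, and 360 to 561 in both. Genes lower with age ranged more widely, from 685 to 1671 in SOC, 601 to 1063 in brain and 266 to 631 in both. Likewise 429 to 934 were higher in SOC than in brain at P4. Between the tissues 581 to 848 were lower at P4 and 759 to 1228 higher and 1202 to 1540 lower at P25. The difference of age changes had 411 to 640 and 764 to 1081. Without the slide 1 array the counts for age in SOC were 1182 and 1087. Without brain replicates 5 and 6 they were 1103 and 758 for age in brain, 556 and 729 at P4, 893 and 1392 at P25 and 509 and 925 for the difference. On the slides with both tissues alone, with slide as a term, they were 1172 and 1143, 1062 and 715, 561 and 581, 896 and 1260, and 522 and 924, in the order of the comparisons.

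Leaving out each sample in turn gave 1058 to 1156 higher and 948 to 1063 lower with age in SOC, 1053 to 1087 and 689 to 747 in brain, and 438 to 459 and 350 to 381 in both. It gave 497 to 560 and 658 to 737 at P4, 863 to 926 and 1294 to 1389 at P25, and 436 to 484 and 824 to 895 for the difference. The number of lists called ranged from 14 to 16, 20 to 22, 18 to 20, 19 to 21 and 22 to 25.

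The direction of camera's test reversed for no list across its threshold. Among called lists the median changed sign for Hox genes at P4 alone, to 0.18 with detection at 13 SDs, where the list was not called (adjusted p = 0.128; 0.00267 to 0.26 over all alternatives). Of 1504 list results for age in SOC 1468 stayed on their side of the threshold, 14 lost and 22 gained a call, and for age in brain these were 1451, 17 and 36. At P4 they were 1445, 35 and 24, at P25 1458, 27 and 19, and for the difference 1448, 20 and 4 of 1472. The calls lost most often were those of synaptic vesicle genes at P4 (13 of 47 settings), meninges genes at P25 (12), the ion pump list with age in SOC (10), cholesterol synthesis with age in brain (8) and monoamine genes at P25 (7) and in the difference (8 of 46). The deposited values ended the calls of the ion pump list with age in SOC, microglia and synaptic vesicle genes at P4, oligodendrocyte precursor genes at P25, and astrocyte and cell division genes in the difference. With the correlation estimated per list 10, 14, 13, 15 and 17 lists were called.

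The change reversed for 9 genes of the lists. With the mean of all probes of a gene it was -0.64 for Ogn and -0.10 for Map6 with age in brain and 0.30 for Hcn3 at P25. With slide as a fixed term it was -0.25 for Fdft1 and 0.44 for Map2 at P4 and -0.12 for Hcrt at P25. With log ratios within arrays it was -0.31 for Spock2 at P4 and -0.55 for Dlx1 at P25. For Pomc at P25 it ranged from -0.26, without SOC P25 replicate 8, to 0.27 when 1 sample was left out. The cause was not tested.

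Whether the replicate numbers pair the samples was not settled. Residuals of samples with the same number had a median correlation of 0.0494 over 36 pairs, 16 of them over 0.1. Pairs of another number, group and slide had a median of -0.0298 over 189 pairs, 41 of them over 0.1. Pairs with a shared slide but no shared array had a median of 0.0494 over 44 pairs, 17 of them over 0.1. A pairing by number therefore cannot be told apart from a shared slide. Of 27 samples 6 correlated best with one of their own number. With the replicate number as a block, a pairing these values do not establish, the counts were 1116 and 1039, 1067 and 711, 529 and 706, 919 and 1382, and 509 and 847, with 16, 23, 20, 21 and 23 lists. Low signal over background limits the dim genes, since 52.4% to 91.6% of probes per sample were above background, and each slide was scanned on 1 day, so a slide term takes up the scan day as well.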

Other observations

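In this part the tests on the other hybridisation of the same RNA and on the P25 channel of slide 1 were chosen only after the results were seen, and a condition on the test of a compressed scale was added after its values were seen.

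The SOC sample from P0 was 1 sample without a replicate, so its values have no error. Across genes, which are not independent replicates, it correlated at 0.977 with the mean of SOC P4, 0.974 with brain P4, 0.946 with brain P25 and 0.929 with SOC P25. Of the 2064 genes changed with age in SOC, 95.0% were nearer to SOC P4 than to SOC P25 in it. Relative to SOC P4 its list medians were -0.63 for myelin, -0.64 for oligodendrocyte precursor, -0.62 for astrocyte and -0.36 for cholesterol synthesis genes. They were -1.32 for meninges and fibroblast genes and 0.16 for immature neuron genes. All other lists lay below 0 too, such as ion pump (-0.38) and synaptic vesicle genes (-0.27), except the brainstem, forebrain, Hox, immediate early and neuropeptide lists. The P0 sample was hybridised in Cy3, and the SOC P4 samples other than replicate 6 in Cy5.

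At P25 the genes not above background in brain that were brightest in SOC were 2 transcripts known only by an accession, which lay near each other on chromosome X of rn4. The first was at 8.76 ± 1.91 in SOC and 6.57 ± 0.25 in brain and at least 4.33-fold higher (limma adjusted p = 0.018). Its spread within SOC was wide at both ages (9.10 ± 1.99 at P4). The call was lost without SOC P25 replicate 2 (adjusted p = 0.0557), SOC P25 replicate 8 (0.059) or brain P25 replicate 2 (0.0574), and without brain replicates 5 and 6 of both ages (0.0745).

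On slide 1 the age difference between SOC P4 replicate 1 and SOC P25 replicate 2, which shared an array, was compressed. On a scale from the SOC P4 mean (0) to the SOC P25 mean (1), the P4 channel of that array lay at 0.308, while the 8 hybridisations of other P4 samples lay between -0.0241 and 0.0553. The P25 channel lay at 0.876, against 1.02 in the other hybridisation of that sample. A different state of the P4 animals was argued against by the other hybridisation of the same RNA, at -0.0518. RNA of the other channel was argued against in the P4 channel alone, where the ratio of the shifts of falling (0.227) and rising genes (0.359) was 0.633 and above the bound set for it. In the P25 channel rising genes lay at 0.957 and falling genes at 0.748, a ratio of their shifts of 0.172, as RNA of the other channel would give, so there it stays a candidate explanation. A compressed intensity scale of that array may explain the shift of the P4 channel, but the value of 0.227 does not decide it, since the P25 channel moved unevenly.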
